A study of Oryza sativa with 52 samples.

How the data were processed

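Total RNA of rice leaves was reverse-transcribed, labelled with Cy3 or Cy5 and hybridised to a custom Agilent two-colour array by the authors, per the labels' protocols. Each channel is a sample of its own: 52 libraries lay on 26 arrays, 2 libraries of opposite dye to an array, with no common reference. The arrays lay on 7 slides, of which 3 held libraries of more than 1 series. Each series had libraries of both dyes. The scanner files were made with Agilent Feature Extraction 10.5.1.1, per the file headers, and hold for each spot and channel the mean intensity, the median intensity of its local background, a processed signal and flags for brightness, saturation and uneven spots. The processed signal was background-subtracted, detrended and dye-normalised by that program, per the file headers. No spot was flagged as saturated in any library. The authors' deposited table of log2 values covers 125722 features and was made with Agilent Feature Extraction and affy, per the submitters' processing notes, which give no order or role. In it, each column ranked the features exactly as the processed signal of that sample's own channel did (Spearman rho of 1), against at most 0.985 for the other channel of the array. Its column medians lay between 6.009 and 6.021, so the channels had been brought to a common distribution. The exact scaling and centring of that table stay unknown, and it was used only as an alternative.

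The mean spot intensities were corrected for background with normexp (offset 50), normalised by loess within arrays with control spots at weight 0, and brought to a common scale by Aquantile between arrays in limma 3.58.1 (R 4.3.3). Control spots and spots flagged as uneven were left out. Spots of one probe were averaged. A probe was tested where it was well above background in at least 4 of the 13 libraries of a series, which 99188 probes were. Levels are normalised log2 intensities and are compared between libraries for the same probe only. A difference of dim probes is understated, since intensity cannot fall below the background. Of the 99188 probes, 1545 had missing values after flagged spots were removed.

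One linear model was fitted to all 52 libraries (lmFit and eBayes with an intensity trend): a mean and a 24 h cosine and sine for each series, and the dye, with the array as a random block. The correlation within arrays was 0.353. Levels of 2 series were compared by contrasts of their means, and rhythms by F tests of the cosine and sine terms. The second morning was tested in a model with 12 clock times, where the correlation within arrays was 0.398. P-values were adjusted by the Benjamini-Hochberg method over all probes tested, with a threshold of 0.05. They measure only the scatter of single libraries around a fitted curve or, for the second morning, around clock-time means shared by the series. An amplitude of 0.5 on the log2 scale is a 2-fold difference between peak and trough. Standard errors of median shifts come from a jackknife that leaves out each of the 13 time points in all series. The time of day of each library was predicted, in steps of 0.25 h, from curves with a 24 h and a 12 h component fitted to the other 3 series. Each library was first centred on the mean of its own series over all time points. The other 3 series include the one sampled on the same day.

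The files give no gene identifier: the gene name of 0 probes differed from the probe's own name and 0 had a description, so none could be looked up among the locus tags and accessions of the reference table. Gene lists fixed before the data were examined were therefore not tested, and the rule for named genes was applied to probes. It took, for each of the 4 level contrasts, the 2 largest rises and the 2 largest falls at an adjusted p under 0.05 with the same direction at 11 or more of 13 matched time points, and for the rhythm the 4 largest amplitudes. Probes of the same strand that overlap by at least 20 bases were taken as 1 set, giving 67160 sets among the probes tested, and 1 probe was named per set. The rule written in advance asked for more genes and for gene symbols. Positions in the genome are not given, because no genome was used here.

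The model was tested on simulated data before use. Values of 97643 probes were simulated and 200 probes per size were changed. For 56 against 36 days, 20% of changes of 0.25 log2 units, 67% of 0.5 and 93.5% of 1 were called, and for the rhythm over all series 62.5%, 92% and 99.5% of the same amplitudes. Of the unchanged probes, 14 and 33 were called in these comparisons. The simulated scatter held an array effect only, without slide offsets or deviations shared by libraries of one clock time. These shares and counts therefore describe the model under its own assumptions, not the rate of errors in these data. Alternatives were the processed signals scaled to their 75th percentile, quantile normalisation, the deposited log2 table, other filters on dim probes, no dye term, no array block, an added 12 h term, the slide as a fixed or random block, the time point as a block, and leaving out libraries. These choices and the tests were fixed before the data were examined, with exceptions added afterwards: the fits without libraries whose time of day stood apart, a fit with the array and the sampling day and hour as random blocks together (correlations of 0.34 and 0.2, probes with no missing value), and the tests of the later peaks near dawn. Explanations tested for the libraries whose time of day stood apart, and for dimmer July arrays, name features seen in the data. These tests were set after those features had been seen, but before their own results. A block for the scan date was not fitted, since all arrays were scanned on 1 day, per the file headers. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the figures.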

Results

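Leaf transcripts of the rice cultivar Koshihikari, a japonica rice grown for its grain in Japan, were measured in a paddy field at Furukawa over the course of 1 day in July and 1 day in August. On each day, plants of an early and a late transplanting, 20 days apart, were sampled every 2 h from 08:00 to 08:00 of the next morning. This gave 4 series of 13 libraries: July at 36 days after transplanting (late) and 56 days (early), and August at 71 days (late) and 91 days (early). No time point was replicated within a series, so the spread behind the tests of level and rhythm is the scatter of the libraries around a fitted 24 h curve. For the second morning it is the scatter around clock-time means shared by the series. The 52 libraries were hybridised to 26 two-colour oligonucleotide arrays, 1 library per dye. Of 151878 probe names, carrying 148841 distinct sequences of 60 bases, 99188 probes were bright enough to be tested. The median raw spot intensity of a library lay between 53.3 and 232 units, and 49.7% to 63.7% of its spots were well above background. The mean share of such spots was 54.6% ± 2.98 (SD, n = 13) at 36 days, 57.6% ± 1.91 at 56 days, 60.7% ± 1.68 at 71 days and 60.3% ± 2.38 at 91 days, each over 13 libraries. The number of arrays limits the precision of all values. The files do not pair the probes with genes, so transcripts are named by probe and by probe sequence, and 2 probes with alike profiles can belong to 1 gene.

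Time of day was the main source of variation among the libraries. The first principal component held 37.4% of the variance, and clock hour accounted for 88.2% of it. The second held 23.7%, of which the month accounted for 56.8%, the series for 62.3% and the slide on which a library was hybridised for 77.8%.

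Over the 4 series together, 84106 of 99188 probes (84.8%) carried a 24 h component at an adjusted p under 0.05, and 30109 of them (30.4% of those tested) rose and fell by at least 2-fold between peak and trough. Peaks were most frequent in the early morning and the late afternoon. Among the 30109 probes, 24.8% peaked from 04:00 to 08:00 and 36.0% from 14:00 to 20:00, while the window from 00:00 to 02:00 held 3.97%. Peaks were about evenly divided between day and night, with 15181 probes peaking from 06:00 to 18:00 and 14928 in the other 12 h. Amplitudes (the distance from the fitted mean to the peak on the log2 scale) reached 1 or more in 9668 probes, 2 or more in 1571 and 3 or more in 336. A fixed slide block gave 74242 calls. One cycle was sampled, so a call is of a 24 h shape within these days.

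**Figure D1:**
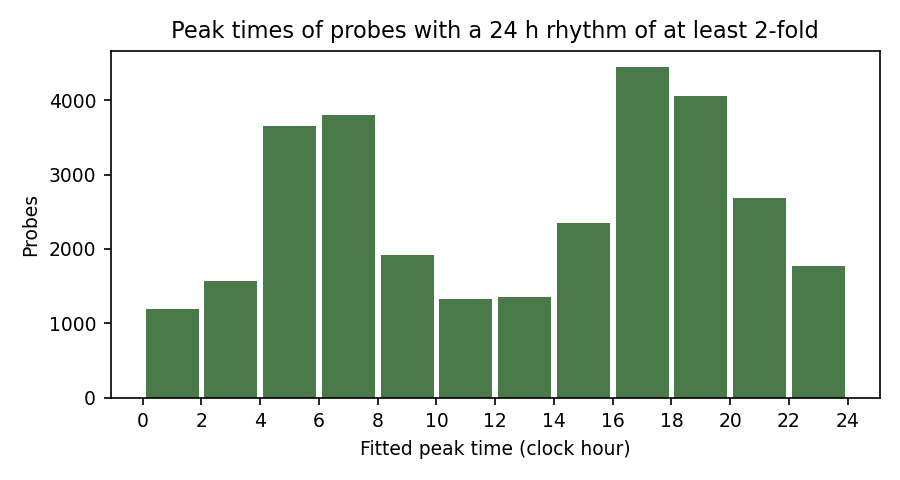
Fitted peak time (clock hour, 2 h windows) of the 30109 probes with a 24 h rhythm of at least 2-fold over all 4 series; bars are numbers of probes. The fullest window, 16 to 18 h, held 4441 probes and the emptiest, 0 to 2 h, held 1194.

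The probe with the largest amplitude, 44kb3_11643 (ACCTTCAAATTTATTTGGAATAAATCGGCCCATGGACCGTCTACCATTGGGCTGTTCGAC), peaked in the early morning, with an amplitude of 5.05 ± 0.16 (SE) log2 units, a fitted peak at 6.37 h and limma adjusted p = 2.36e-26. Its mean level was 16.44 ± 0.21 (SD, n = 4 series) at 06:00 and 6.79 ± 1.05 at 18:00, where 1 of 4 libraries was well above background, so the depth of the trough is a lower bound. A second dawn probe, 44kb3_960 (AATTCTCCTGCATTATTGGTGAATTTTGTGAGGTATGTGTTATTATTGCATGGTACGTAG), followed nearly the same course, with an amplitude of 5.02 ± 0.16, a peak at 6.41 h and adjusted p = 5.91e-27. An overlapping probe gave an amplitude of 4.85. An afternoon probe, eAry2_48790 (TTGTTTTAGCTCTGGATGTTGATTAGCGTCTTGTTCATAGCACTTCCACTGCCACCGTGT), had an amplitude of 4.87 ± 0.31 and a peak at 15.5 h (adjusted p = 3.59e-17). It fell from 18.30 ± 0.59 at 14:00 to 8.63 ± 1.77 at 04:00 (SD, n = 4) and was well above background in all 52 libraries. A night probe, eAry2_38876 (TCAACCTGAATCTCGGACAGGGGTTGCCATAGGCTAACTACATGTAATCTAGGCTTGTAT), had an amplitude of 4.76 ± 0.23 and a peak at 2.77 h (adjusted p = 4.64e-21). Its mean level was 16.31 ± 0.33 at 02:00 and 7.02 ± 0.23 at 14:00, and both of its overlapping probes had amplitudes between 4.59 and 4.68.

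**Figure D2:**
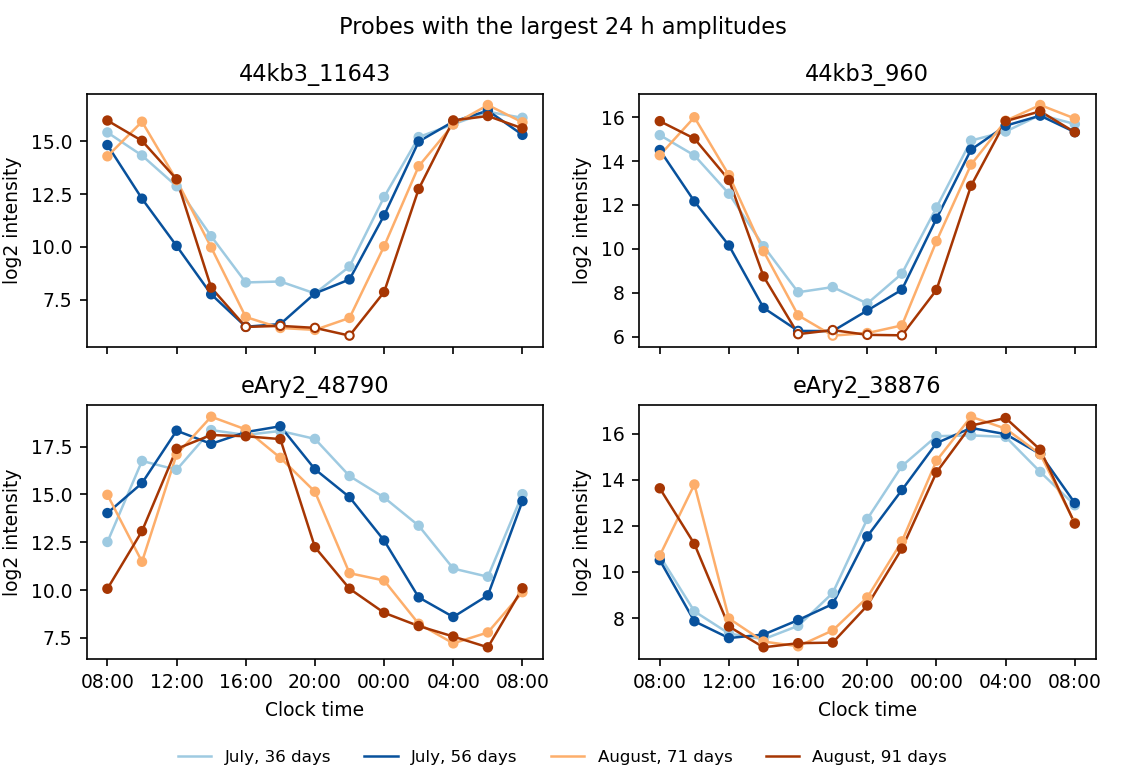
Normalised log2 intensity against clock time for the 4 probes with the largest 24 h amplitudes; 1 point per library, 1 line per series, open circles not well above background, and y axes that differ between panels. Both upper probes stood near 16 at 06:00 in every series and near the background at 18:00 in 3 of the 4 series, and eAry2_38876 peaked at night.

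A 24 h component was called for 63575 probes at 36 days, 59848 at 56 days, 61795 at 71 days and 63247 at 91 days, and for 39759 probes in all 4 series. Of the 30109 probes with a rhythm of at least 2-fold, 25046 were called in every series. The median amplitudes of all 30109 probes were 0.82, 0.78, 0.85 and 0.89 log2 units in the same order of series. For these 25046 probes, plants sampled on the same day peaked at nearly the same hour whatever their age: 96.8% of peaks at 56 and 36 days lay within 2 h of each other, and 97.2% of those at 91 and 71 days. Between months the share within 2 h was 78.5% to 86.8%. The median difference was −0.0314 h for 56 minus 36 days and 0.232 h for 91 minus 71 days, against 0.475 to 0.714 h for the 4 differences of August minus July. Under a fixed slide block the numbers of calls lay further apart, with 51645, 47122, 38794 and 56383 at 36, 56, 71 and 91 days. The series were spread differently over the slides, so these counts do not measure a difference between the stages.

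Between the months, the 24 h curve of 26060 probes differed in amplitude or timing at an adjusted p under 0.05 (mean of both August series against mean of both July series), and the difference curve reached an amplitude of at least 0.5 log2 units for 10333. Fitted peaks came later in August over much of the day in the early transplanting, and most so around dawn. For the 6731 probes with a peak from 04:00 to 08:00 over all series, the median shift was 1.26 ± 0.28 h (jackknife SE over 13 time points) in the early transplanting and 0.90 ± 0.31 h in the late one. The same probes shifted by −0.0664 ± 0.198 h between 56 and 36 days in July and by 0.297 ± 0.305 h between 91 and 71 days in August, each within its error. In the early transplanting the shift also exceeded 2 SE for probes peaking from 00:00 to 04:00 (0.455 ± 0.210 h), from 12:00 to 16:00 (0.522 ± 0.192 h) and from 16:00 to 20:00 (0.714 ± 0.317 h). The late transplanting gave 0.569 ± 0.397, 0.710 ± 0.530 and 0.421 ± 0.683 h in these windows, each within 2 SE. With the slide as a fixed block, the early shifts in these windows were 0.618 ± 0.468, 0.765 ± 0.291 and 0.921 ± 0.509 h. Of these, only that from 12:00 to 16:00 exceeded 2 SE. The late shifts turned negative under this block, at −0.569 ± 1.14, −0.712 ± 0.940 and −0.210 ± 0.792 h, each within 2 SE. From 20:00 to 24:00 the early shift was 0.278 ± 0.218 h without the block and 1.08 ± 0.527 h with it, beyond 2 SE only with it. The late shift in that window was −0.0175 ± 1.01 h with the block. The amplitude of probes peaking from 08:00 to 12:00 rose in the early transplanting, with a median log2 ratio of 0.35 ± 0.12, against 0.11 ± 0.12 in the late one. The fitted peaks of all 3 named night and dawn probes lay later in August. The fitted peak of 44kb3_11643 lay at 6.17 and 5.27 h in July and at 6.91 and 7.01 h in August (adjusted p of the difference = 0.000214), and that of eAry2_38876 at 1.95 and 1.96 h in July and at 3.45 and 3.69 h in August (adjusted p = 0.00167). The highest measured value of both dawn probes was at 06:00 in every series. That of eAry2_38876 was at 02:00 at 36, 56 and 71 days and at 04:00 at 91 days. These shifts are therefore of the fitted curve, and the highest library moved little or not at all. The afternoon probe eAry2_48790 did not pass this test (adjusted p = 0.0997). A fixed slide block gave 8172 calls, and the median shift of the dawn probes was 1.51 ± 0.428 h in the early and 0.709 ± 0.402 h in the late transplanting, beside 0.864 ± 0.513 h between 91 and 71 days on the same August day. Without the 2 displaced 71-day libraries as well, these 3 shifts were 1.53 ± 0.419, 0.599 ± 0.338 and 0.978 ± 0.417 h, so that under this block plants of the same day differed too. Without an array block, 40015 probes were called, and with the sampling day and hour as a random block beside the array, 20896.

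**Figure D3:**
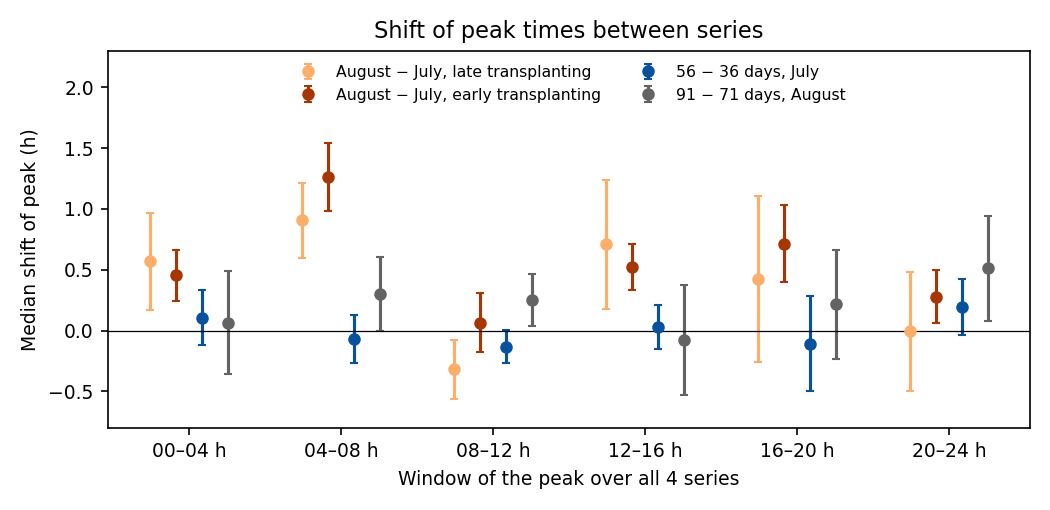
Median shift of the fitted peak time (h) between 2 series, by the 4 h window in which a probe peaked over all series; error bars are jackknife SE over the 13 time points. August minus July lies above 0 by more than 2 SE from 04 to 08 h in both transplantings (0.905 and 1.26 h) and, in the early one, also from 00 to 04, 12 to 16 and 16 to 20 h; between transplantings on one day the values reach 0.511 h, within 2 SE of 0.

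Few probes differed between transplantings in the shape of the day. The 24 h curve of 63 probes differed between the early and the late series at an adjusted p under 0.05 (5114 at an unadjusted p under 0.05, 5.16% of those tested), and none of the 4 named rhythmic probes was among them. The count depended on single time points: between 8 and 70 were called when 1 time point was left out, with 8 when the second 08:00 libraries were left out and 70 without those of 06:00. Under a fixed slide block 3 were called, and with the sampling day and hour as a random block beside the array, 169.

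The comparison of 56 with 36 days in July sets plants of both transplantings against each other on the same day and in the same weather. Of 99188 probes, 17158 were higher and 15709 lower at 56 days (adjusted p under 0.05), with a median change of 0.39 log2 units, and 1264 were higher and 1356 lower by at least 2-fold. The balance of directions turned with the scaling: processed signals gave 14813 higher and 18878 lower. Of the 2620 probes called at 2-fold, 2066 differed in the same direction at all 13 matched time points. PPNTnpc_01705 (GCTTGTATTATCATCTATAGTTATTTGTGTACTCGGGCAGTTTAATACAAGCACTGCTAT) rose by 4.95 ± 0.28 (SE) log2 units, from 8.79 ± 0.75 at 36 days to 13.76 ± 0.87 at 56 days (SD over 13 time points, which includes the daily course; adjusted p = 7.03e-17). PPNTpc_00175 (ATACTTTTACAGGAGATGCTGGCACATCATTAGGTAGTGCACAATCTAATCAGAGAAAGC) rose by 4.82 ± 0.39 to 11.57 ± 1.11, from a level well above background in 5 of 13 libraries (adjusted p = 1.08e-12). The largest falls were those of 44kb3_4764 (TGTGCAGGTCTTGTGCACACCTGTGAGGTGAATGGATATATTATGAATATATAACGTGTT), from 13.66 ± 1.5 to 8.37 ± 1.49 (difference −5.32 ± 0.65, adjusted p = 2.33e-08), and 44kb3_20070 (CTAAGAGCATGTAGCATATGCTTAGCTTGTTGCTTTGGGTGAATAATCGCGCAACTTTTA), from 13.19 ± 1.54 to 8.04 ± 1.44 (difference −5.17 ± 0.64, adjusted p = 3.28e-08). The 4 probes that overlap 44kb3_4764 differed by −5.30 to −5.11. All 4 named probes kept their direction at 13 of 13 time points.

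Slide and series overlapped in part: 7 slides held the 52 libraries, and 3 slides held libraries of more than 1 series. With the slide as a fixed block, 820 probes were called for 56 against 36 days (290 higher and 530 lower), with a median SE of 0.26 in place of 0.10 log2 units, and as a random block 21566 were called. Of the 820, 727 were also called, in the same direction, without the block. PPNTnpc_01705 then rose by 4.21 (adjusted p = 0.00422), while PPNTpc_00175 (3.26, adjusted p = 0.125), 44kb3_4764 (−5.42, adjusted p = 0.144) and 44kb3_20070 (−5.11, adjusted p = 0.168) no longer passed. Within the slide that held both series, the 36-day library of the second 08:00 was set against the 56-day library of the first, which also differ in day and dye: 96.4% of the 2708 probes called at 2-fold from all other libraries had the same sign, and the correlation across all probes, which are not independent replicates, was 0.649. Differences between the 2 mornings of one series gave correlations of −0.189 to 0.102 with the same contrast. The slide with both series held 1 library of 36 days and 7 of 56 days. Level differences of 56 against 36 days under a fixed slide block rest on that 1 library of 36 days. The comparison within the slide uses it too and is not separate support for that fit.

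In August, 13081 probes were higher and 11244 lower at 91 than at 71 days, 801 and 1172 of them by at least 2-fold, with a median change of 0.40 log2 units. Processed signals turned the balance, with 11341 higher and 12813 lower. The probe 44kb3_38262 (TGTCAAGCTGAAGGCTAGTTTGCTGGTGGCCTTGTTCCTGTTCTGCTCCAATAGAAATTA) rose by 4.10 ± 0.20 (SE), from 6.94 ± 0.52 to 11.04 ± 0.98 (SD over 13 time points; adjusted p = 4.04e-19), and stood at 6.51 ± 0.24 and 6.63 ± 0.19 in July. A rise of 3.99 ± 0.46 was measured for eAry2_20417 (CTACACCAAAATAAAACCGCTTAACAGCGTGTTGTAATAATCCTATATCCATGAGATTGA), from 8.68 ± 0.81 to 12.73 ± 0.52 (adjusted p = 1.15e-08). The largest falls were those of 44kb3_10697 (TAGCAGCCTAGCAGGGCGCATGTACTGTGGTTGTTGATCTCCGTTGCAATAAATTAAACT), from 12.38 ± 2.48 to 8.15 ± 1.27 (difference −4.51 ± 0.53, adjusted p = 1.73e-08), and eAry1_09990 (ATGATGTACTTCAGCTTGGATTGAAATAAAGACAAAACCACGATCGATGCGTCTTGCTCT), from 10.28 ± 1.25 to 6.79 ± 0.52, a level well above background in 8 of 13 libraries (difference −3.68 ± 0.35, adjusted p = 8.02e-11). A fixed slide block gave 2485 calls (852 higher and 1633 lower) and a random one 14296. Under the fixed block 44kb3_38262 rose by 3.73 (adjusted p = 0.000165), 44kb3_10697 differed by −5.88 (0.0177) and eAry1_09990 by −5.65 (0.000235), and eAry2_20417 no longer passed (2.02, adjusted p = 0.335). Within the slide that held both series, the 91-day library of the first 08:00 against the 71-day library of the second, again of another day and dye, gave the same sign for 92.7% of the 1861 probes called at 2-fold, with a correlation across all probes of 0.554. The 2 mornings of one series gave −0.127 to 0.284.

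Plants of one transplanting date differed widely between the July and the August day, between which age, day length and weather all changed. In the late transplanting, 28735 probes were higher and 26063 lower in August, 3958 and 3928 of them by at least 2-fold, with a median change of 0.47 log2 units. Processed signals turned the balance here too, with 23967 higher and 31957 lower. The probe 44kb3_23620 (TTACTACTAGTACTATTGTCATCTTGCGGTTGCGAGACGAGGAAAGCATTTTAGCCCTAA) rose by 7.37 ± 0.17 (SE), from 7.57 ± 0.68 at 36 days to 14.93 ± 0.49 at 71 days (SD over 13 time points; adjusted p = 7.07e-33). Its level was 11.40 ± 0.76 at 56 days and 15.11 ± 0.36 at 91 days, where the difference from 71 days did not pass the test (0.19, adjusted p = 0.44). Cuffnpc_00332 (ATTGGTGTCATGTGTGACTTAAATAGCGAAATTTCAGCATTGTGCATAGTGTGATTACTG) took a like course, with a rise of 7.09 ± 0.17 (adjusted p = 4.57e-32), from 7.48 ± 0.63 to 14.57 ± 0.47. The largest falls were those of 44kb3_1576 (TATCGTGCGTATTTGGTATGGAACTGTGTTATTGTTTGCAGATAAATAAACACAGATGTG), which stood at 14.73 ± 1.27, 11.50 ± 1.48, 8.87 ± 1.52 and 7.85 ± 1.30 at 36, 56, 71 and 91 days (August minus July −5.86 ± 0.23, adjusted p = 2.14e-23), and of eAry2_39854 (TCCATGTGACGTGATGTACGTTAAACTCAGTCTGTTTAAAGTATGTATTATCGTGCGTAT), with a difference of −5.86 ± 0.24 (adjusted p = 9.05e-23). Both also followed the day, with peaks at 12.1 and 12.2 h and amplitudes of 1.81 ± 0.12 and 1.91 ± 0.12. The sequence of eAry2_39854 ends with the bases that open 44kb3_1576, an overlap shorter than the 20 bases that define a set. Both probes may therefore measure the same transcript.

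**Figure D4:**
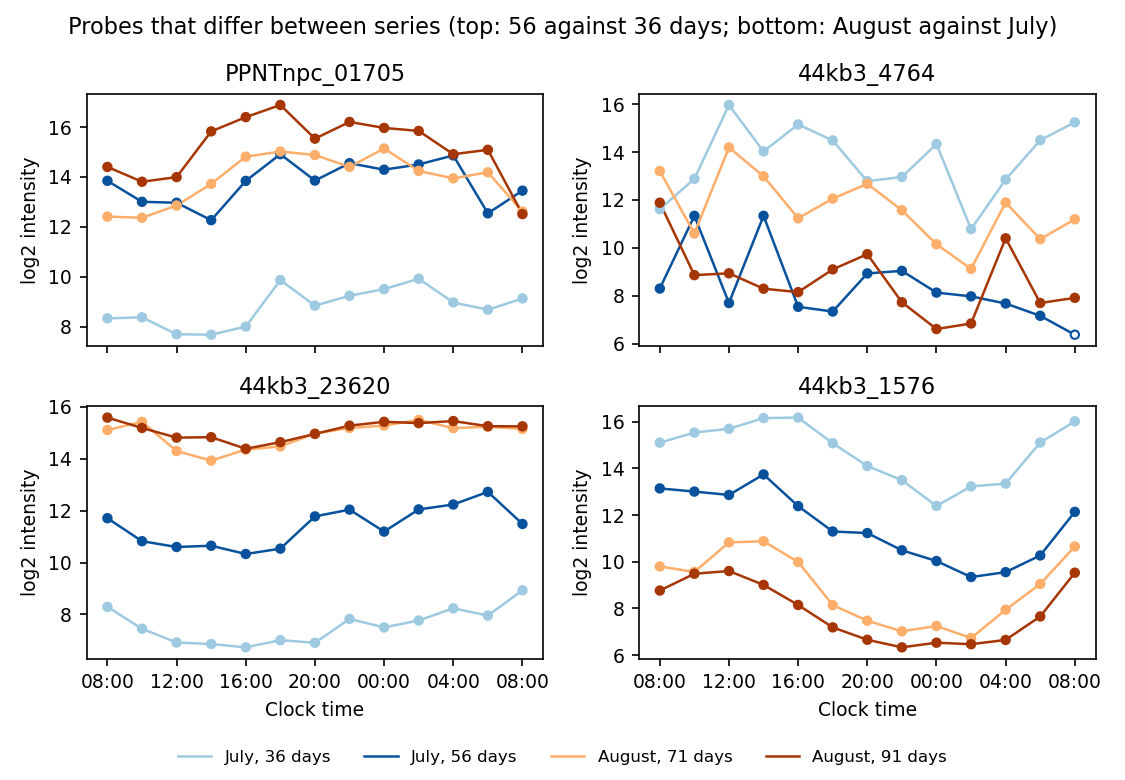
Normalised log2 intensity against clock time for 2 probes that differed between 56 and 36 days (top) and 2 that differed between August and July in the late transplanting (bottom); 1 point per library, open circles not well above background, and y axes that differ between panels. The mean level of 44kb3_23620 was 7.57, 11.40, 14.93 and 15.11 at 36, 56, 71 and 91 days, and that of 44kb3_1576 was 14.73, 11.50, 8.87 and 7.85.

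In the early transplanting, 29087 probes were higher and 29171 lower in August, 5027 and 4547 of them by at least 2-fold, with a median change of 0.49 log2 units, and processed signals gave 26247 higher and 32995 lower. The probe eAry2_44367 (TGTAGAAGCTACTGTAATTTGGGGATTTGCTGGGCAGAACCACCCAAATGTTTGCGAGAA) rose by 5.92 ± 0.20 (SE), from 6.90 ± 0.60 at 56 days, where 8 of 13 libraries were well above background, to 12.83 ± 0.39 at 91 days (SD over 13 time points; adjusted p = 6.22e-26). A rise of 5.51 ± 0.11 was measured for 44kb3_10988 (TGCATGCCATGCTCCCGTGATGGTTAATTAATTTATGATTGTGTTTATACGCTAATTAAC), from 6.40 ± 0.24 to 11.89 ± 0.55 (adjusted p = 5.05e-35). It was well above background in 2 of 13 libraries at 56 days and 0 of 13 at 36 days, and an overlapping probe gave 3.56. The largest falls were those of maskBest_07473 (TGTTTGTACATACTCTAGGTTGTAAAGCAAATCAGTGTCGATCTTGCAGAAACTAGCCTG), from 13.92 ± 1.01 to 8.25 ± 0.69 (difference −5.82 ± 0.41, adjusted p = 1.28e-15), and eAry1_15483 (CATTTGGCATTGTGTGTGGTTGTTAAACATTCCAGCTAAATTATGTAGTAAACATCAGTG), from 14.14 ± 1.04 to 8.56 ± 0.78 (difference −5.73 ± 0.42, adjusted p = 3.14e-15). All 8 probes named for the months kept their direction at 13 of 13 time points, and under a fixed slide block all 8 passed, with changes between −6.35 and 7.15 log2 units and adjusted p between 4.89e-15 and 0.0167. Since some of them may measure the same transcript, these need not be 8 separate results.

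With the slide as a fixed block, 1233 probes were called between the months in the late (869 higher and 364 lower) and 5601 in the early transplanting (3471 higher and 2130 lower), with a median SE of 0.39 and 0.30 in place of 0.10 log2 units, and as a random block 42908 and 47727. Of all probes called without the block, 80.8% and 87.1% had the same sign with it, and of those called at 2-fold, 92.8% and 95.5%. No slide held both series of either comparison. The 1 slide with libraries of both months held 71-day and 56-day plants, and single libraries of 08:00 on it gave a correlation of 0.298 across all probes with the same difference from all other libraries, where differences between the 2 mornings of one series gave up to 0.303. Of the 5500 probes called at 2-fold from the other libraries, 73.4% had the same sign, with a median difference of 0.82 for the rises and −0.22 for the falls. The 2 libraries differ in dye, and the 71-day one is among those whose time of day stood apart. All level differences between months with a fixed slide block, those of the 8 named probes included, rest on this slide, whose 2 August libraries are the pair whose time of day stood apart. In the late transplanting they rest also on the 1 library of 36 days that shared a slide with 56-day libraries.

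The effect of the month differed between the transplantings for 23327 probes (interaction, adjusted p under 0.05), 3325 of them by at least 2-fold. The change from July to August was higher in the early than in the late transplanting for 11898 of them and lower for 11429. A fixed slide block called 1248 (580 higher and 668 lower), a random one 10417, and the deposited values 9394 higher and 10890 lower. Both month effects use different libraries, and their log2 differences correlated across probes (Pearson r = 0.747, Spearman rho = 0.715). Nearly all July libraries lay on other slides than those of August, however. An offset between these slides would enter both month effects alike, so their agreement is not independent replication. The counts for independent lists do not allow for this. Of the probes called in both, 19801 were higher in August in both transplantings, against 8427 for independent lists, 17806 were lower in both, against 7665, and 1429 went opposite ways, against 16094. The 2 age effects, also from different libraries, correlated less (Pearson r = 0.266, Spearman rho = 0.176): 4026 probes were higher in the older plants of both months, against 2263 for independent lists, 3596 were lower in both, against 1781, and 1936 went opposite ways, against 4017. Another 4 correlations were computed between contrasts that share a series. They lay between 0.0727 and 0.661, and between −0.218 and 0.502 with the time points divided so that no library entered both contrasts. Probes are not independent replicates.

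The libraries of 08:00 on the second morning differed from those of the first by no probe at an adjusted p under 0.05 in limma, with 8399 probes (8.47%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.0505. Other ways of normalising called 22, 17 and 13 probes.

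Each library's time of day could be read from its transcripts, taken relative to the mean of its own series. Predicted from the 24 h and 12 h curves of the other 3 series over the 2000 most rhythmic probes, the hour lay within 1 h of the label for 48 of 52 libraries and within 1.5 h for 50, with a median absolute difference of 0.25 h. The 71-day library labelled as the first 08:00 was read 1.75 h late and the one labelled 10:00 was read 2.25 h early, and both shared 1 array. The 91-day libraries labelled 00:00 and 02:00 were read 1.25 and 1.5 h early. The 56-day library labelled 10:00 had the lowest correlation with the predicted curve, 0.829, against a median of 0.963. Without the first pair of libraries 84085 probes were rhythmic over all series, and 54753 were called between months in the late transplanting and 24254 between 91 and 71 days, and without the 56-day library 84896, 56288 and 26118.

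**Figure D5:**
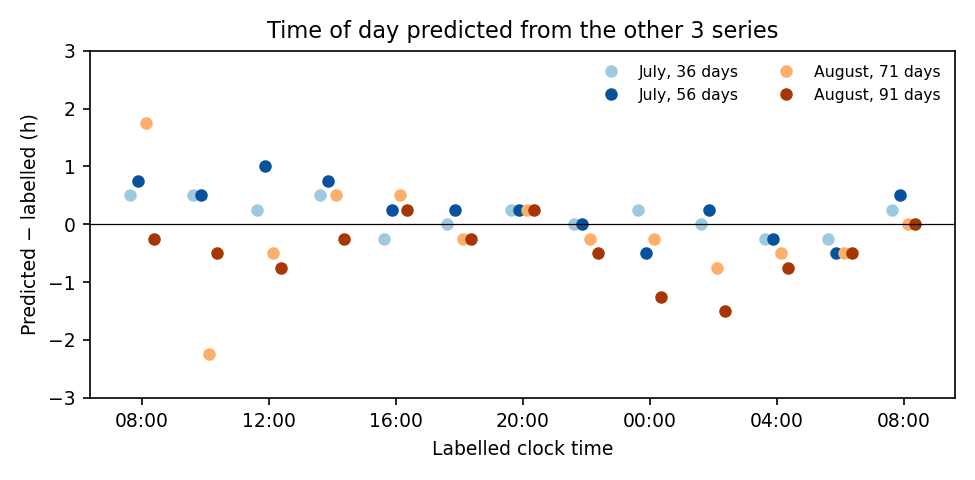
Predicted minus labelled clock time (h) for each of the 52 libraries, with the prediction made from the other 3 series; 1 point per library, colours are series, and points of one time are set side by side. The 71-day libraries labelled 08:00 (first) and 10:00 lie at 1.75 and −2.25 h, and the other 50 lie within 1.5 h of their label.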

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

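The 3 tests of the later peaks near dawn were set after the shift had been seen, and the other tests in this part were set before.

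The effect of the month differed between the transplantings for 23327 probes, the 24 h rhythm differed between the months for 26060 probes and between the transplantings for 63, each by a test of the difference itself. Among the named probes, the signed change from July to August in the early transplanting lay above that in the late one by 4.95 log2 units for eAry2_20417, by 3.98 for 44kb3_38262, by 2.21 for eAry2_44367, by 2.14 for 44kb3_1576 and by 2.00 for eAry2_39854. The last 2 probes fell in both transplantings, and less in the early one. The signed change in the early transplanting lay below that in the late one, with differences of −3.80 for eAry1_09990, −3.67 for Cuffnpc_00332, −3.63 for 44kb3_23620, −3.56 for PPNTnpc_01705, −3.36 for maskBest_07473, −3.31 for eAry1_15483, −2.59 for PPNTpc_00175 and −0.81 for 44kb3_10988. Each of these probes was chosen as an extreme of a level contrast that enters this difference, so signs and sizes lean with that choice. Differences of probes near the background in July rest on levels that were in part not measured: of 13 libraries at 36 and 56 days, 0 and 2 were well above background for 44kb3_10988, 1 and 5 for eAry1_09990, 4 and 8 for eAry2_44367, 5 and 9 for 44kb3_38262, and 5 and 13 for PPNTpc_00175. The curve of the difference between the August and July rhythms had an amplitude of 2.05 log2 units for eAry2_38876, 1.89 for 44kb3_11643 and 1.78 for 44kb3_960.

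The 71-day libraries labelled 08:00 (first) and 10:00 were read 1.75 h after and 2.25 h before their labelled times. Dye bias on their array stays open: with the 33598 probes whose dye effect over all arrays had an unadjusted p above 0.5 the mean displacement was 2 h, but this choice of probes moved no library by more than 0.25 h and does not bear on a bias of 1 array. An exchange of the labels 08:00 and 10:00 within that array may explain it: over rhythmic probes, the library labelled 10:00 correlated better with the second 08:00 of its series than the library labelled 08:00 did (difference of correlations 0.126), where the other 3 series gave −0.0116, −0.25 and −0.675. This comparison largely restates the displacement, since any cause of it would give the same sign, so it does not single out an exchange. With the libraries of an array in order of series and time, Cy5 came first on 12 of the 13 August arrays and Cy3 on this one, as on all 4 arrays of its slide, so the dye order does not decide. The labels were kept as given, a delay of the plants themselves was not tested, and the exchange stays a hypothesis.

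The wide difference in level between August and July may come in part from the slides. Single libraries on the 1 slide with both months gave a correlation of 0.298 with the difference from all other libraries, too close to the 0.303 reached by 2 mornings of one series to decide, and one of the libraries is in doubt. July arrays were dimmer, but the share called among the brightest 24797 probes was 0.964 times that of all probes in the late and 1.06 times in the early transplanting, so dimness was not decided either. The dimmest 24797 probes were called least, at 0.890 times the share of all probes in the late and 0.773 times in the early transplanting, which goes against dimness, but they also were for 91 against 71 days (0.774 times), where no July array enters, so dim probes are called less whatever the contrast. Slide, dimness, age and season therefore cannot be told apart for most of these probes.

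Fitted peaks near dawn came later in August, and in the early transplanting so did fitted peaks in 3 other windows of the day. With the slide as a fixed block, only the window from 12:00 to 16:00 among these 3 stayed beyond 2 SE (0.765 ± 0.291 h). The early shift from 20:00 to 24:00 passed 2 SE only under this block (1.08 ± 0.527 h). Whether the shift is particular to dawn therefore stays open. In the early transplanting, whose series hold neither displaced library, the shift of 1.26 ± 0.28 h argues against those libraries as its cause, a shift of 1.51 ± 0.428 h with the slide as a fixed block (1.53 ± 0.419 h without the displaced libraries as well) argues against offsets between slides as its whole cause, and a lowest value of 1.08 h with any time point left out argues against a single time point. In the late transplanting the same tests leave all of them open: 0.749 h without the displaced libraries, 0.709 ± 0.402 h with the slide block and 0.639 h at the lowest, with a jackknife SE of 0.307 h. Under the slide block the 91-day plants also peaked after the 71-day plants of the same day, by 0.864 ± 0.513 h, and by 0.978 ± 0.417 h without the displaced libraries, so how much of the shift belongs to the month stays open. Day length, plant age and weather stay open as untested explanations for the early transplanting.

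Regrouping the libraries at random, on the 97643 probes with no missing value, left the real count unreached for most comparisons. These splits treat single libraries as exchangeable, although series were not replicated and slides ran in order of time. Free regrouping also moves real differences between series into the scatter, which lowers the other counts. The splits therefore do not exclude chance differences between series or days, nor drift or slide offsets. For 56 against 36 days the real grouping gave 32529 calls and was 1 of 100 splits that reached it, with 10150 as the highest of the others. For 91 against 71 days it gave 24054 (1 of 100, highest other 6860), for August against July 54118 in the late (1 of 100, highest other 39687) and 57597 in the early transplanting (1 of 100, highest other 35391). The interaction gave 23069 and the difference in rhythm between months 25851 (1 of 50 each, highest other 0). With the clock times shuffled within each series, the rhythm gave 83107 calls over all series and 62935, 59282, 61162 and 62593 in the 4 series by age (1 of 40 each), against 5124, 419, 64, 14 and 2537 as the highest others. For the rhythm between transplantings, 2 of 50 splits reached the real count of 66, and 1 of them called 4224 probes, which points to a structure of the libraries that was not identified. For the second morning, 11 of 35 splits of the 08:00 libraries reached the real count of 8 on these probes (0 over all probes tested), so chance is not excluded. One split called 4208, and which one was not recorded. The 35 include splits that set July against August libraries, where a difference between the months at 08:00 can raise the count. They are therefore no measure of chance alone.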

How the results depend on the processing

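The settings that leave out the libraries whose time of day stood apart, and the one with the array and the sampling day and hour as random blocks together, were chosen after seeing the data. Of the counts under other settings, 305 stayed within 1.5 times the reported one and 49 did not. Of 553 values of named probes under other settings, 549 kept their direction and passed the threshold, 4 kept their direction without passing it and 0 reversed. The fit without the second 08:00 libraries enters both tallies 2 times, on its own and among the time points left out in turn. The deposited table lists fewer probes, so 3 named probes have no value there. With the slide as a fixed block, counts fell to 820 (56 against 36 days), 2485 (91 against 71 days), 1233 and 5601 (August against July, late and early), 1248 (interaction), 38794 (rhythm at 71 days), 8172 (rhythm between months) and 3 (rhythm between transplantings). Standard errors grew and estimates moved too: level changes with and without the block correlated at 0.620 to 0.737 across probes. With the slide as a random block, 21566, 14296 and 10417 were called for 56 against 36 days, 91 against 71 days and the interaction, and 106 for the rhythm between transplantings. Requiring a 2-fold difference left by construction 2620, 1973, 7886 and 9574 probes in the 4 level contrasts, 3325 in the interaction, 30109 rhythmic over all series, 32248, 29624, 32358 and 33590 in the series by age, 10333 between months and 26 between transplantings. Without the array block the rhythm between months gave 40015 calls. The rhythm between transplantings, 63 calls as reported, moved in most settings: 20 with processed signals, 24 with the deposited values, 29 with no filter on dim probes, 25 with probes above background in all 13 libraries of a series, 353 without the array block, 268 with a 12 h term, 8 without the second 08:00 libraries, 29 without the 2 displaced 71-day libraries and 169 with the sampling day and hour as a random block beside the array. The second morning, 0 calls as reported, gave 22 with processed signals, 17 with quantile normalisation, 13 with the deposited values, 7 with probes above background in all 13 libraries of a series and 8 without the displaced libraries. The cause of these moves was not tested unless given.

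Leaving out each time point in turn in all series gave 28991 to 32724 calls for 56 against 36 days, 19509 to 25836 for 91 against 71 days, 52290 to 55887 and 55616 to 58416 for August against July (late and early), 18793 to 23797 for the interaction, 82919 to 84054 for the rhythm over all series, 60992 to 63516, 55931 to 60255, 57586 to 62611 and 60158 to 62608 in the series by age, 21142 to 27231 between months and 8 to 70 between transplantings. In the last, leaving out 1 of 10 time points moved the count by over 1.5 times: 30 without the first 08:00, 39 without 10:00, 37 without 12:00, 32 without 14:00, 33 without 16:00, 21 without 18:00, 22 without 00:00, 33 without 02:00, 32 without 04:00 and 8 without the second 08:00.

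Libraries with the same number share a clock time, and within a month also the sampling day. Of 78 pairs with the same number, 77 deviated from their series means with a correlation over 0.1 (median 0.725, lowest 0.0457), and 108 of 156 best matches in another series had the library's own number. Of the residuals from the 24 h curves, 65 of 78 pairs correlated over 0.1 (median 0.266), so libraries of one clock time share deviations from the curve. With the sampling day and hour as a random block beside the array, the rhythm between months gave 20896 calls and the levels of 56 against 36 and 91 against 71 days 37342 and 29114. With the time point as a block in place of the cosine, 33624, 23319, 54677, 57719 and 23116 probes were called in the 4 level contrasts and the interaction, and 72970 for the rhythm over all series. Signal over background limits the dim probes: at their lower level, some named probes were above background in only a part of the libraries. A median over the probes of a gene, all alternatives of the gene list tests and a block for the scan date were not run, and the values within single slides are single differences with no count of calls.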

Other observations

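A 12 h component was called for 32027 probes beside the 24 h one, but reached an amplitude of 0.5 log2 units in 1279 and exceeded the 24 h component in 110. Of these 110, 41 peaked from 08:00 to 10:00 and 34 from 10:00 to 12:00, and again 12 h later.

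Probes whose sequences share at least 20 bases in opposite orientation numbered 1686 pairs on the array and 892 pairs among the probes tested. In 85 pairs both probes had a rhythm of at least 2-fold. Their peaks differed by a median of 3.59 h, with 28.2% within 1 h of each other and 36.5% more than 6 h apart, against 10.1% and 49.5% of random pairs of rhythmic probes. Overlapping probes of the same strand, in 14421 rhythmic pairs, had a median difference of 0.0742 h and 99.5% within 1 h, and their changes from July to August in the late transplanting correlated at 0.968 across pairs, which gives the precision of these values between overlapping probes.

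The share of probes tested and rhythmic differed with the class that the probe name gives, whose meaning the files do not state. Of the probes named 44kb3_, 81.9% were tested and 34.2% of those tested had a rhythm of at least 2-fold. The same shares were 74.5% and 28.0% for 44kb3Koshi_, 61.1% and 29.7% for eAry1_, 64.7% and 31.2% for eAry2_, 57.1% and 23.6% for maskBest_, 54.5% and 18.6% for PPNTnpc_, 52.7% and 20.5% for PPNTpc_, 63.5% and 15.4% for eAryKoshi_, and 29.7% and 14.3% for Cuffnpc_. The median level of the probes tested was 9.29, 8.69, 8.54, 8.86, 7.70, 7.17, 7.22, 7.52 and 6.76 log2 units in the same order, and the shares were not adjusted for it.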
